A study of Mus musculus with 4 samples.

How the data were processed

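RNA of primary mouse keratinocytes was hybridized to oligonucleotide arrays in 4 groups of 1 array each, per the labels: fresh cells of embryos at 15.5 days of gestation, fresh cells of mice 2 days old, newborn cells infected with an adenovirus for activated Notch1 and GFP, and newborn cells infected with a GFP control adenovirus. The values deposited by the authors are probe set intensities on a linear scale, with 1 column per array. Between 18.3% and 19.8% of values per array were below 0, as arises when a background or mismatch signal is subtracted. The 2% trimmed means of the arrays ran from 2478 to 2486, a difference of 0.328%, so the deposited intensities appear to have been brought to a common mean. The software, the scaling target and any detection calls were not given in the sources used here. The median intensities were 543.7 on the embryonic, 554.9 on the newborn, 680.8 on the array labelled Notch1 and 609.8 on the GFP array.

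The table held 12487 probe sets, of which 66 array controls were left out of all gene results. Of the other 12421 probe sets, the platform annotation paired 10832 with 1 gene symbol, 396 with several and 1193 with none, and only those with 1 symbol were named. The gene identifiers of 10816 of the 10832 were found in a RefSeq gene table of the assembly GRCm38.p6, used for names only, and 0 symbols changed. These probe sets stand for 8250 genes, 2073 of them with several probe sets. No coordinates are given, since the build behind the array design was not given in the sources used here.

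Because the trimmed means lay within 5% of each other, the deposited intensities were used as they were. Values below the 40th percentile of the 4 arrays pooled, 284, were set to that floor before log2. A gene was represented by its probe set with the highest mean intensity over the 4 arrays and was measured in a comparison if it lay above the floor on at least 1 of both arrays. Where 1 array was at the floor, the ratio is a lower bound, written as "at least". A ratio with 1 array just above the floor is printed as a plain fold and is uncertain too. Genes were counted as higher or lower at 2-fold or more. With 1 array per group there was no test, and the number of arrays limits the precision. As an internal error, the SD of the log2 ratio between measured probe sets of a gene was computed. It leaves out differences between animals, cultures and hybridizations.

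Gene lists, 24 with 737 entries of which 570 were on the array, were fixed before the data were examined, as were the groups, comparisons, named genes and 10 alternatives. They covered epidermal differentiation, the basal layer, other keratins, the Notch pathway, caspases and apoptosis, proliferation, cell cycle inhibitors and G1 cyclins, interferon and antigen presentation, immediate early and stress genes, Wnt, hedgehog and hair follicle genes, the lipid barrier, cholesterol synthesis, fetal and imprinted genes, matrix and TGF-beta, ribosomal proteins, housekeeping genes, and markers of fibroblasts, endothelium, melanocytes, immune cells, skeletal muscle, red cells, nerve and Schwann cells, and fat cells. The median log2 ratio of a list was placed among the medians of 10000 random lists of the same size matched on mean intensity in 20 bins, and a list was called higher or lower above percentile 97.5 or below percentile 2.5, as a description of these arrays. Alternatives used 2000 random lists.

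The named genes of a comparison were the 12 highest and 12 lowest log2 ratios among genes above the floor on both arrays, the 5 largest bounds in each direction, up to 4 members with the largest absolute log2 ratio of each list with at least 4 measured members, and Notch1, Hes1, Hey1, Krt1, Krt10, Ivl, Lor, Krt5, Krt14, Cdkn1a and Trp63. Not every list member under this rule is printed, and 1 further gene fixed in advance is not reported here. Overlaps were set beside the product of both list sizes divided by the number of genes measured in both.

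The alternatives fixed in advance were scaling to a common median or 75th percentile, quantile normalization, a floor at the 20th or 60th percentile, an offset in place of a floor, only genes above the floor on both arrays, the median over all probe sets of a gene, and a criterion of 1.5-fold or 3-fold. After the data were seen, 2 more were added: centring of the log2 ratio by a lowess curve on mean log2 intensity with a fraction of 0.3, and leaving out genes above an intensity of 20000. List medians were recomputed under 10 settings, 8 of those fixed in advance and the 2 added, since the fold criterion does not enter a median; a list left with fewer than 3 measured members under a setting was not placed there. Further lists of G1/S genes, G2/M genes, NF-kB targets and simple epithelium genes were drawn up after the data were seen and serve the closing observations only.

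The counting and list steps were tested on simulated arrays in which 200 genes were changed by known folds. The changed genes were drawn from those above an intensity of 568 on the newborn or GFP array. Recovery of dimmer genes was therefore not simulated. For the embryonic and newborn pair the simulated SD of the log2 ratio was 0.45. There, 89.5% of genes changed 3-fold were recovered among 5747 genes and 98.5% of those changed 8-fold among 5742 genes. In these runs 2.61% and 2.74% of unchanged genes passed 2-fold. For the infected cultures the simulated SD was 0.65, below the 0.69 measured between probe sets. There, 78.5% of genes changed 3-fold were recovered among 5873 genes and 97% of those changed 8-fold among 5892 genes. In these runs 11.9% and 11.8% of unchanged genes passed 2-fold. For each pair, 100 lists were drawn at random from all measured genes of the 8-fold run, changed ones included. Of these, 7 fell outside the central 95% for each pair. Random lists lie mostly inside by construction, so this checks the calculation and not lists whose members vary together. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9.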

Results

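Transcript levels were measured in primary mouse keratinocytes, the main cell type of the epidermis, on 4 oligonucleotide arrays. The first array held RNA of keratinocytes taken fresh from embryos at 15.5 days of gestation, and the second RNA of keratinocytes taken fresh from mice 2 days old. The third held RNA of newborn keratinocytes infected with an adenovirus that carried an activated form of Notch1, a cell surface receptor, together with green fluorescent protein (GFP), and the fourth RNA of newborn keratinocytes infected with a control virus carrying GFP. Each group had 1 array, so no difference could be set against a spread between replicates, no p-value was computed, and each fold describes a pair of arrays. The spread between probe sets of a gene served as the error within an array pair. Its SD on the log2 scale was 0.46 over 795 genes for embryonic against newborn cells. For the pair of infected cultures it was 0.69 over 816 genes. The spike-in controls, added RNA that no cell makes, also differed within pairs. For embryonic over newborn, BioB, BioC, BioDn and CreX had mean log2 ratios of 0.75, 0.59, 0.41 and -0.17. Between 58.4% and 62.2% of the 12421 probe sets that were not array controls lay above the intensity floor of 284 on an array.

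Embryonic keratinocytes were set against newborn keratinocytes to see how cells of skin that was still forming differed from cells of skin after birth. Keratins were among the largest differences: Krt19 was at least 46.6-fold higher on the embryonic array, Krt7 16.6-fold, Krt8 at least 9.90-fold and Krt15 at least 7.89-fold. Krt7, Krt8 and Krt19 are keratins of simple epithelia, and Krt15 is a keratin of basal and hair follicle cells. Krt1, a keratin of differentiating epidermal cells, was 2.58-fold lower on the embryonic array, and the hair keratin Krt36 at least 13.6-fold lower. The Krt36 probe set read -2473.4 on the embryonic array, far below 0, so its ratio is uncertain. Genes of cell division were higher on the embryonic array and markers of fibroblasts and melanocytes lower.

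Of 5939 genes measured on this pair, 452 were at least 2-fold higher on the embryonic array and 316 at least 2-fold lower, together 12.9%. Among genes above the floor on both arrays, Nrep was 10.8-fold higher, the glutathione transferase Gsta4 7.13-fold, Psca 7.03-fold, the mitotic kinesin Kifc1 6.93-fold and the cell cycle inhibitor Cdkn1c 6.63-fold. The desmosomal cadherin Dsc2 was 6.46-fold higher, Igfbp3 6.34-fold, Anapc4 5.36-fold, the tight junction protein Cldn3 5.28-fold, Anln 5.23-fold and Crnkl1 5.22-fold. Acadm was at least 8.59-fold and Foxo4 at least 5.44-fold higher. In the other direction, Dntt was 9.53-fold lower on the embryonic array, Slc10a6 8.38-fold, Flvcr2 8.10-fold, 2610528A11Rik 7.64-fold, xanthine dehydrogenase Xdh 5.598-fold and Vegfd 5.12-fold. Ly6g6c was 4.90-fold lower, Itln1 4.41-fold, H2-T18 4.30-fold, Thbd 4.07-fold and Crabp1 3.99-fold, and Slpi was 4.91-fold lower by its brightest probe set while another of its probe sets had a log2 ratio of 0.21. Cyp2b10 was at least 14.7-fold lower, the interferon-induced gene Ifi27 at least 13.98-fold, and the collagen VI genes Col6a3 and Col6a2 at least 9.07-fold and 6.95-fold. Newborn intensities of Kifc1 (309.8) and Crnkl1 (332.4) lay just above the floor. So did embryonic intensities of Itln1 (291.6), H2-T18 (296.6) and, of genes given below, Tchh (320.2). The folds of these genes are therefore uncertain, although they are not written as bounds.

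The median of 7 of the 24 gene lists lay outside the central 95% of matched random lists. Independently drawn genes would put 1.2 lists outside. That value does not allow for list members that vary together or for differences between single arrays, so it is not an expectation for unchanged cells. The proliferation list was the one on the higher side: 9 of its 42 measured members were at least 2-fold higher on the embryonic array and 0 lower, with a median log2 ratio of 0.41 at percentile 99.99. Racgap1, a regulator of cytokinesis, was at least 5.37-fold higher, the kinesin Kif20a 3.46-fold, Hmgb2 2.95-fold and topoisomerase Top2a at least 2.48-fold. Fibroblast markers were lower, with 9 of 19 at least 2-fold lower, 0 higher and a median of -0.91, Bgn being 3.63-fold lower. All 7 melanocyte markers lay below 0, 3 of them by at least 2-fold, with a median of -0.92; Pmel was 3.09-fold, Kit at least 2.27-fold and Tyrp1 2.05-fold lower. Both marker lists stand beside every group of this comparison as a measured difference between the preparations.

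Interferon and antigen presentation genes had a median of -0.52, with 4 of 16 at least 2-fold lower and 1 higher. Besides Ifi27, Irf9 was at least 5.21-fold lower on the embryonic array, Ifi35 2.82-fold and Mx2 at least 2.36-fold. Immediate early and stress genes had a median of -0.28, with 2 of 32 lower by at least 2-fold and 1 higher; Fos was 2.63-fold and Dusp1 2.39-fold lower, and the chaperone Hsp90aa1 2.78-fold higher. Lipid barrier genes had a median of -0.47, with 2 of 18 lower and 1 higher. Degs2, which makes ceramides of the skin barrier, was 3.63-fold lower, the lipoxygenase Aloxe3 2.02-fold lower, and Elovl6 at least 2.24-fold higher. Epidermal differentiation genes had a median of -0.19 at percentile 1.41, with 5 of 32 lower and 3 higher: trichohyalin Tchh was 3.21-fold and S100a8 2.68-fold lower, and Krt77 2.72-fold higher. This last list was inside the central 95% under 5 of the 10 settings in which list medians were recomputed, and the lipid barrier list was inside it with a floor at the 20th percentile, where its median was -0.12.

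The other 17 lists lay inside the central 95% of random lists. Basal layer genes had a median of -0.11, with 1 of 17 higher, and other keratins a median of 0.10, with 5 of 14 higher and 2 lower; without genes above an intensity of 20000 the keratin list was on the higher side, with a median of 1.28 at percentile 100. Cell cycle inhibitors and G1 cyclins had a median of 0.30, with 4 of 18 higher. Matrix and TGF-beta genes had a median of 0.18, with 6 of 26 higher and 2 lower; Col4a1 was 4.20-fold, Col4a2 2.77-fold and Sparc 2.73-fold higher. In the Notch pathway list, 1 of 22 genes was higher and 0 lower, with a median of -0.02. Of the caspases and apoptosis genes, 1 of 18 was higher, with a median of 0.00. Wnt, hedgehog and hair follicle genes had a median of -0.28, with 4 of 29 lower, among them Tcf7l2 at least 5.49-fold. This list was on the lower side under 4 of the 10 settings, with medians between -0.35 and -0.51. Cholesterol synthesis genes had a median of -0.16 and 0 of 16 beyond 2-fold, fetal and imprinted genes one of 0.23 with 2 of 13 higher, ribosomal proteins one of -0.10 with 1 of 18 higher and 1 lower, and housekeeping genes one of -0.06 with 0 of 15 beyond 2-fold. Markers of other cells had medians of -0.30 for endothelium (0 of 5 beyond 2-fold), -0.57 for immune cells (1 of 9 lower), -0.19 for skeletal muscle (3 of 17 higher and 1 lower), -0.40 for red cells (0 of 4), -0.03 for nerve and Schwann cells (2 of 9 higher) and -0.46 for fat cells (1 of 3 higher). Under 1 setting each, the cell cycle inhibitor and nerve lists were on the higher side and the cholesterol synthesis and immune cell lists on the lower side.

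Several genes fixed in advance differed little between embryonic and newborn cells. Hes1 had a log2 ratio of 0.21, Krt10 one of 0.13, involucrin (Ivl) one of 0.29, loricrin (Lor) one of -0.12, Cdkn1a one of -0.12 by its brightest probe set and -0.64 by another, and the basal cell factor Trp63 one of -0.17. Both Ivl intensities, 395.8 on the embryonic and 323.4 on the newborn array, lay near the floor, so its small ratio is uncertain. Hey1 was above the floor on the embryonic array only, with a log2 ratio of at least 0.46. The brightest Notch1 probe set gave 0.38 and the other -0.45, so no direction was given for Notch1. Krt5 and Krt14, the main keratins of basal cells, were at or below the floor on all 4 arrays and their probe sets were not informative. The share of genes beyond 2-fold was 28.6% at mean intensities between 568 and 1000 and 5.64% between 5000 and 20000, so the counts hold many dim genes. Folds are those of the brightest probe set, and other probe sets gave log2 ratios of 4.04 for Krt19, 2.81 for Kif20a, -1.15 for Thbd, -1.05 for Bgn and -0.09 for Tyrp1.

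**Figure D1:**
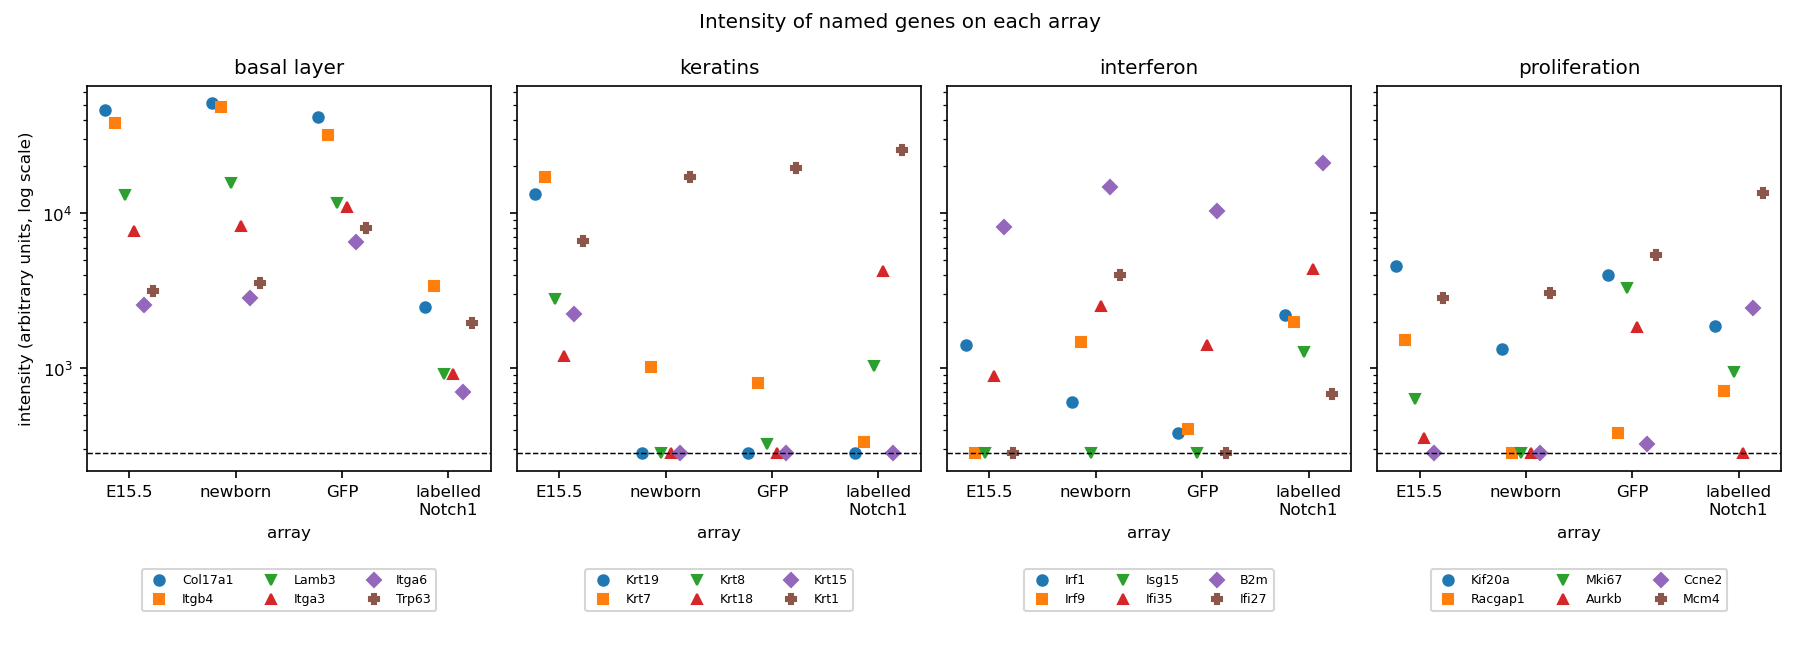
Intensity in arbitrary units on a log axis, for 6 genes each of the basal layer, keratin, interferon and proliferation groups, on the 4 arrays; each symbol is 1 gene, and values at or below the dashed floor of 284 are drawn on it. The basal layer genes lie lowest on the array labelled Notch1, where Col17a1 was 16.9-fold below the GFP array, and Krt19 lies above the floor on the embryonic array only.

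The culture infected with activated Notch1 was set against the GFP control culture to see which genes differed with Notch1 signalling. Notch1 itself was read first, as a check of the label, and went against it: its brightest probe set was at 5879 on the array labelled Notch1 and 19049 on the GFP array, 3.24-fold lower, and its other probe set had a log2 ratio of -1.36. The position of these probe sets relative to the activated fragment was not given in the sources used here, and a probe set outside the fragment would check nothing. Each direction below is therefore given for the array labelled Notch1. The basal layer list, which includes genes that anchor basal keratinocytes to the basement membrane, was lower on that array. The interferon and antigen presentation list and the cholesterol synthesis list were higher. For both higher lists the GFP array stood below the fresh newborn array as well.

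Of 15 measured basal layer genes, 11 were at least 2-fold lower on the array labelled Notch1 and 0 higher, with a median log2 ratio of -2.07 at percentile 0 of matched random lists. Collagen XVII (Col17a1) was 16.9-fold lower, the laminin chain Lamb3 12.8-fold, integrin alpha 3 (Itga3) 11.995-fold and integrin beta 4 (Itgb4) 9.34-fold; other probe sets gave log2 ratios of -1.30 for Itga3 and -2.71 for Lamb3. Trp63, a transcription factor of basal cells, was 4.10-fold lower. This list kept its side under all 10 settings in which list medians were recomputed. Among single genes, follistatin (Fst) was 52.0-fold lower, Map4 19.01-fold, the protease Htra1 18.9-fold, filaggrin (Flg) 17.0-fold, Casq2 12.5-fold, the Notch ligand Dll1 11.4-fold, tenascin C (Tnc) 11.2-fold, Prss23 10.3-fold and Scmh1 10.04-fold. Wnt4 was at least 27.98-fold lower, the prostaglandin synthase Ptgs2 at least 20.2-fold, Ackr3 at least 13.7-fold, Rad1 at least 10.03-fold and Krt36 at least 9.24-fold.

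On the higher side, Fxyd5 was 17.97-fold, Znrd1 16.2-fold and Notch3, another Notch receptor, 10.96-fold higher on the array labelled Notch1. A4galt was 9.85-fold higher, Chchd10 8.91-fold, Sec14l2 8.65-fold, Ina 8.34-fold, the tight junction protein occludin (Ocln) 8.32-fold, Art3 8.10-fold, metallothionein Mt2 8.10-fold, Plpp1 7.56-fold and cyclin E2 (Ccne2) 7.54-fold. Gosr1 was at least 15.9-fold higher, the simple epithelial keratin Krt18 at least 15.0-fold, Igkv14-111 at least 13.7-fold, Lmbr1l at least 10.8-fold and Upp1 at least 8.69-fold. These are values of the brightest probe set, and other probe sets gave smaller log2 ratios of 0.39 for Upp1, 1.37 for Lmbr1l and 1.19 for Plpp1. Krt8, the partner of Krt18, was 3.18-fold higher. The GFP intensities of Fxyd5 (287.7), Notch3 (298.6), Ocln (304.8), Plpp1 (310.5), Krt8 (323.8), Ccne2 (325.6) and Chchd10 (328.2) lay just above the floor. So did those of Msx1 (289.4) and Scel (305.2), whose folds are given below. The folds of all these genes are therefore uncertain, although they are not written as bounds. Of 6128 genes measured on this pair, 686 were at least 2-fold higher and 689 at least 2-fold lower, together 22.4%. In the simulations for this pair, with an SD of 0.65, 11.9% and 11.8% of unchanged genes passed 2-fold. For the embryonic and newborn pair, with an SD of 0.45, the shares were 2.61% and 2.74%. The 22.4% is therefore not a share of changed genes, and the counts of both pairs are not directly comparable. Scaling the arrays to a common median moved the median of all genes by -0.15 and the split to 521 higher and 865 lower, so that 37.6% in place of 49.9% of these genes were higher. Scaling to a common 75th percentile moved it the other way, to 765 higher and 598 lower, or 56.1% higher.

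Interferon and antigen presentation genes had a median log2 ratio of 0.84 at percentile 99.97, with 7 of 21 at least 2-fold higher and 0 lower. Irf1 was 5.74-fold higher on the array labelled Notch1, Irf9 4.94-fold, the ubiquitin-like protein Isg15 at least 4.49-fold and Ifi35 3.05-fold. The fresh newborn array had a median of 0.53 over the GFP array for this list, at percentile 96.4 and so inside the central 95%, with Irf9 3.67-fold higher. Cholesterol synthesis genes had a median of 0.58 at percentile 99.92, with 3 of 16 higher and 0 lower; Idi1 was 2.69-fold, Mvk 2.43-fold and squalene epoxidase (Sqle) 2.36-fold higher, and Dhcr7 had a log2 ratio of -0.999. The fresh newborn array was also higher than the GFP array for these genes, with a median of 1.13 at percentile 100; this array pair was compared after the data were seen. Notch pathway genes had a median of 0.49 at percentile 98.74, with 4 of 23 higher and 3 lower. Beside Notch3, the receptor Notch4 was at least 3.03-fold higher and the target gene Hey1 at least 2.13-fold, while the target Hes1 had a log2 ratio of 0.71 and Notch1 and Dll1 were lower. The Notch pathway list was inside the central 95%, with a median of 0.35, when genes at the floor on 1 array or genes above an intensity of 20000 were left out.

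Ribosomal protein genes had a median of 0.99 at percentile 100, with 9 of 18 at least 2-fold higher and 1 lower; Rpl41 was 3.07-fold and Rpl19 2.98-fold higher, and Rpl22 at least 7.31-fold lower. The fresh newborn array was also higher than the GFP array for this list, with a median of 0.76 at percentile 99.8. This array pair was compared after the data were seen. The brightest genes stood higher as a class on the array labelled Notch1 than on the GFP array, with a median of 0.34 over the 316 genes of a mean intensity above 20000. The highest intensity was 60410 on the GFP array, against 80054 on the embryonic, 83371 on the newborn and 91206 on the array labelled Notch1. The CreX spike-in control had a mean log2 ratio of 0.80, while the dimmer BioB, BioC and BioDn controls had -0.67, -0.51 and -0.37. Leaving out genes above 20000 took out most members of the list, and the median over those left, among them Rps27 and Rps29, was -0.21. That median does not describe the bright members. Across the 24 lists, 4 lay on the higher and 1 on the lower side, where independently drawn genes would put 1.2 outside, with the limit given above.

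The other 19 lists lay inside the central 95%. Epidermal differentiation genes went both ways, with 5 of 33 higher and 11 lower and a median of -0.03: Sprr2f was 8.48-fold, Sprr2d 3.71-fold, loricrin (Lor) 3.31-fold and involucrin (Ivl) 2.13-fold lower, and Scel 3.93-fold higher. Krt1 had a log2 ratio of 0.40 and Krt10 one of 0.65. Without genes above an intensity of 20000 the median of this list was -0.84, at percentile 0. Proliferation genes also went both ways, with 5 of 42 higher and 7 lower and a median of -0.13. The mitotic kinase Aurkb was at least 6.50-fold and Ube2c at least 6.26-fold lower, while Mki67 was 3.47-fold lower by its brightest probe set and had a log2 ratio of 0.74 by another. Of the cell cycle inhibitors and G1 cyclins, 1 of 20 was higher and 4 were lower, with a median of 0.21; Gadd45a was 6.42-fold and Ccnd2 3.84-fold lower, Cdkn2d 3.58-fold higher, and Cdkn1a had a log2 ratio of 0.64. Caspases and apoptosis genes had a median of -0.07, with 4 of 23 higher and 2 lower; Casp8 was 3.11-fold higher and Bid 3.44-fold lower.

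Other keratins had a median of 0.53, with 4 of 12 higher and 3 lower; without genes above an intensity of 20000 this list was on the higher side, with a median of 0.81. The median was 0.09 for immediate early and stress genes, with 4 of 29 higher and 6 lower, Myc being 4.22-fold lower. Wnt, hedgehog and hair follicle genes had a median of 0.07, with 5 of 30 higher and 6 lower; Tcf7l1 was at least 7.73-fold, with a log2 ratio of 1.62 by another probe set, and Msx1 4.98-fold higher. Lipid barrier genes had a median of -0.03, with 2 of 20 higher and 4 lower, Alox12b being at least 4.75-fold lower. Matrix and TGF-beta genes had a median of -0.14, with 3 of 25 higher and 5 lower, among them Tgfbi at least 5.46-fold lower and the protease Plau 3.77-fold lower. Fetal and imprinted genes had a median of 0.07, with 3 of 13 higher and 1 lower, and housekeeping genes one of 0.40, with 2 of 15 higher. Markers of other cells had medians of 0.36 for fibroblasts (1 of 17 higher and 2 lower), 0.45 for endothelium (1 of 6 higher), 0.44 for melanocytes (0 of 8 beyond 2-fold), -0.02 for immune cells (2 of 9 higher), 0.30 for skeletal muscle (3 of 17 higher and 2 lower), 0.39 for red cells (1 of 6 higher), 0.18 for nerve and Schwann cells (1 of 9 higher and 1 lower) and 0.12 for fat cells (2 of 6 lower). At mean intensities between 568 and 1000, 39.0% of genes were beyond 2-fold, against 13.7% between 5000 and 20000, and 13 genes had probe sets beyond 2-fold in opposite directions.

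**Figure D2:**
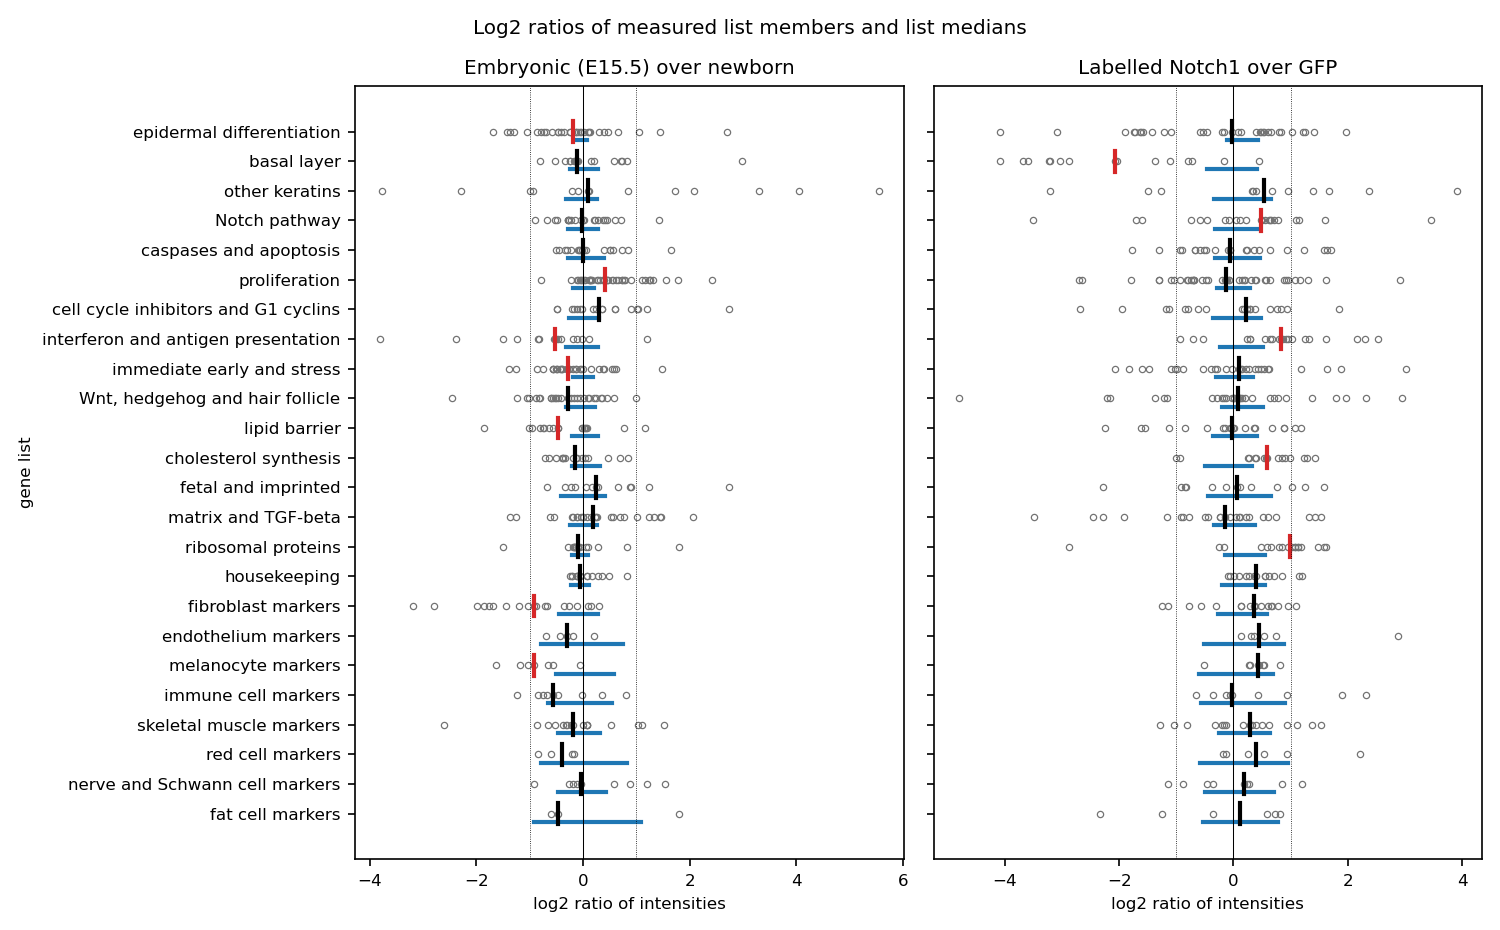
Log2 ratios of intensities for the measured members of the 24 gene lists (open circles), embryonic over newborn at the left and the array labelled Notch1 over GFP at the right; thick ticks are list medians, red where they lie outside the central 95% of matched random lists, which the blue bars span. The basal layer median of -2.07 at the right is the farthest from 0, and the fibroblast and melanocyte medians of -0.91 and -0.92 are the lowest at the left.

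Both comparisons were set side by side over the 5652 genes measured in each; they share no array. Krt8, Krt18 and Ocln were at least 2-fold higher on the embryonic array and also on the array labelled Notch1, as were Gsta4, Acadm, the tight junction gene Cldn7 and the desmosomal gene Dsg2. Igfbp3 and Krt7 and the cell division genes Kifc1, Kif20a, Anln and Birc5 were higher on the embryonic array and lower on the array labelled Notch1. The interferon genes Irf9, Ifi35 and Ifi27 were lower on the embryonic array and higher on the array labelled Notch1. Xdh, Wnt3a and Degs2 were lower on both, as was Krt36 by the probe set that read far below 0 on the embryonic array. These examples were chosen after their values were seen.

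In all, 67 genes were higher in both, where independent lists of these sizes gave 46.2, and 40 were lower in both, where they gave 34.1. In opposite directions, 75 genes were higher on the embryonic array and lower on the array labelled Notch1, where independent lists gave 52.0, and 57 were lower and then higher, where they gave 30.4. All 4 overlaps thus lay above the value for independent lists, including those in opposite directions. That value does not allow for intensity. At mean intensities between 568 and 1000, 28.6% and 39.0% of genes passed 2-fold in the respective comparisons. Between 5000 and 20000 the shares were 5.64% and 13.7%. The excess therefore cannot be read as a link between the comparisons. Across genes, which are not independent replicates, the log2 ratios had a Pearson r of -0.0012 and a Spearman rho of -0.0036.

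**Figure D3:**
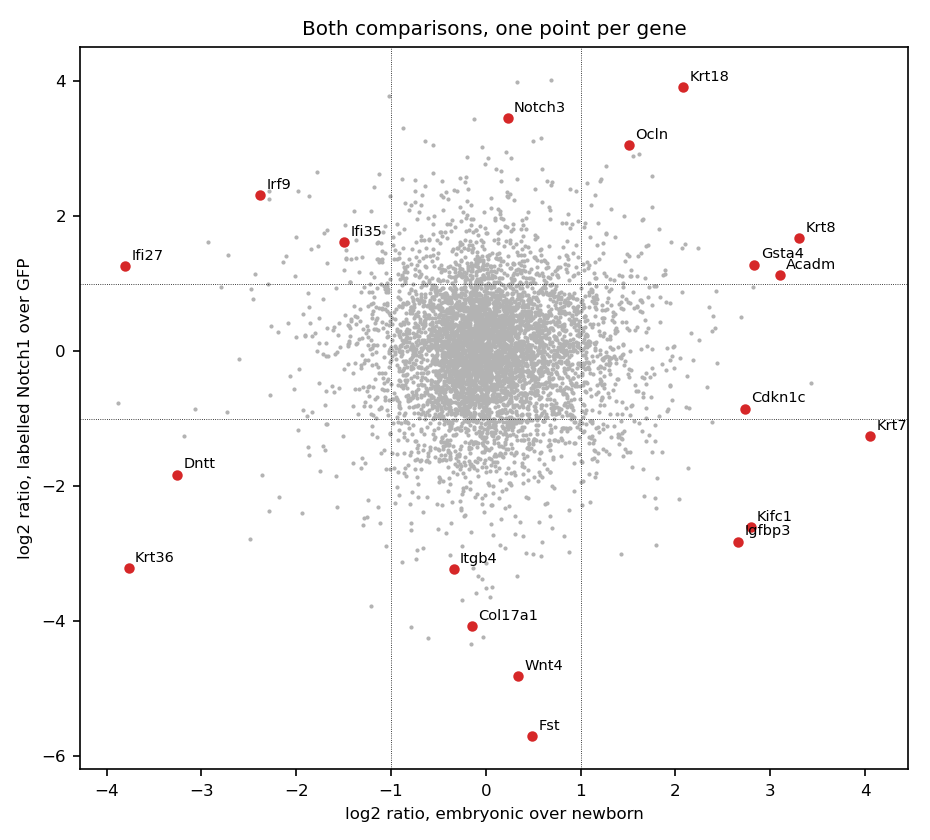
Log2 ratio of the array labelled Notch1 over GFP against that of embryonic over newborn, with 1 point for each of the 5652 genes measured in both comparisons; red points are named genes and dotted lines mark 2-fold. The cloud has no slope, with a Pearson r of -0.0012 across genes, and Krt8 and Krt18 lie at the upper right.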

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

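The tests of the spike-in controls, of newborn against GFP cells, of Notch target genes, of the Notch1 probe position, of the spread of fibroblast markers and of other cell markers were chosen after the result was seen; the tests of ribosomal proteins after centring and of fibroblast markers with a higher floor were written before their results. Control probe sets for mouse transcripts entered no comparison, and those at least 2-fold higher on the embryonic array or the array labelled Notch1 are given first. On the array labelled Notch1 the 18S ribosomal RNA probe sets were 3.47-fold, 5.55-fold and 6.93-fold higher than on the GFP array. Beta actin control probe sets were 2.59-fold and 2.24-fold higher, and Gapdh control probe sets 2.56-fold, 2.24-fold and 2.02-fold higher. A transferrin receptor control probe set was at least 2.28-fold higher on the embryonic than on the newborn array and 2.97-fold higher on the array labelled Notch1 than on the GFP array. Other controls went both ways: on the array labelled Notch1 the MurFAS probe set had a log2 ratio of at most -2.14 and an antisense BioDn probe set one of -1.32, while antisense Gapdh and actin probe sets had log2 ratios of 1.26 and 1.12 and a PheX probe set one of at least 1.10. On the embryonic array a pyruvate carboxylase control had a log2 ratio of at most -1.42 and the yeast URA3 control one of at most -1.01.

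Actin and Gapdh control probe sets and most ribosomal protein genes stood higher on the array labelled Notch1. A compressed top of the intensity scale on the GFP array may account for part of this: the CreX spike-in, added RNA that no cell makes, also had a mean log2 ratio of 0.80, while the dimmer BioB had one of -0.67. BioC had one of -0.51 and BioDn one of -0.37. BioDn was itself bright, with means of 18653 on the array labelled Notch1 and 21745 on the GFP array. Compression as the whole cause could not be decided. After intensity-dependent centring the ribosomal protein median was still 0.64, at percentile 100. But centring shifts the intensity-matched lists too (excess over them 0.75 before and 0.67 after), so this test could hardly turn out otherwise. Leaving out genes above 20000 gave -0.21, but that took out the bright ribosomal protein genes in question and decides nothing about them. For 18 ribosomal protein genes the GFP array was not level with the newborn array. Newborn over GFP had a median of 0.76, at percentile 99.8 (matched random lists 0.36). For these genes that argues against a change of the array labelled Notch1 alone, with the GFP array level with the newborn array. Whether the intensity scale or the cells set the GFP array apart could not be decided. The CreX spike-in had a mean log2 ratio of 0.76 on that pair too, and fresh cells differ from infected cultures in several ways. For 15 housekeeping genes the newborn over GFP median was 0.58, at percentile 91.4, inside the central 95%. A change of the array labelled Notch1 alone could not be decided for them. The 18S control probe sets stood apart on the array labelled Notch1, at 9139 to 10604 against 1089 to 3712 on the other arrays. An effect of Notch1 on ribosomal protein genes stays open and untested.

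The Notch1 probe sets were lower on the array labelled Notch1. An exchange of this array with the GFP array may be the cause and could not be decided. Known Notch targets had a median log2 ratio of 0.78 over 5 measured genes, with a standard error of 0.39 from the spread between probe sets. Without Notch3, whose high value had drawn attention, it was 0.74 over 4 genes with a standard error of 0.43. These errors rest on the mean variance between probe sets, an SD of 0.69. The median variance gave an SD of 0.39 and so would give smaller errors. Hes5 and Hey1 were near or at the floor on the GFP array. Hes1 and Notch3 were also higher on the newborn array than on the GFP array, by 0.63 and 3.23 on the log2 scale, whereas Notch1 itself differed by 0.07 there, so that for Notch1 the array labelled Notch1 stood apart. The probe sets may lie outside the expressed part of Notch1, but 0 of them had a probe sequence in the sources used here, so this could not be decided. Lower transcription of the cells' own Notch1 gene under the activated form stays open as a biological explanation and was not tested.

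Fibroblast and melanocyte markers were lower on the embryonic array. A smaller share of fibroblasts may be the cause, but the log2 ratios of 10 fibroblast markers above the floor on both arrays had an SD of 0.82, against 0.46 between probe sets, which neither bears out nor excludes 1 common factor. The 0.46 rests on the mean variance between probe sets. The median variance gave an SD of 0.26, against which the markers spread far more widely, so the reading depends on that choice. With the floor at the 60th percentile the median was -1.19 over 9 fibroblast markers. Noise of dim probe sets could not be decided by this, since a marker stays when it passes the floor on the newborn array alone. A smaller share of every cell type other than keratinocytes could not be decided, since 44 markers of endothelium, immune cells, muscle, red cells and nerve had a median of -0.20, at percentile 12.6, with members on both sides and many near the floor. The difference in age between embryo and newborn stays open as a biological explanation.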

How the results depend on the processing

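The alternatives with intensity-dependent centring and without genes above 20000 were chosen after the data were seen. No paired analysis was possible because each group had 1 array. With a floor at the 20th percentile the counts went from 452 higher and 316 lower to 1101 and 1009 for embryonic against newborn cells, and from 686 and 689 to 1414 and 1294 for the array labelled Notch1 against GFP; with the 60th percentile they were 165 and 107, and 283 and 384, since the floor sets how many dim genes are measured. The 1.5-fold criterion gave 1018 and 825, and 1454 and 1317, and the 3-fold criterion 117 and 92, and 244 and 246, by construction. The overlaps (main values 67 higher in both, 75 higher then lower, 57 lower then higher, 40 lower in both) were, in this order, 266, 230, 307 and 238 at the 20th percentile floor, 18, 21, 11 and 17 at the 60th, 37, 47, 32 and 24 with only genes above the floor on both arrays, 256, 243, 218 and 195 at 1.5-fold and 9, 10, 10 and 8 at 3-fold; the offset in place of a floor gave 43 genes higher then lower. Each of these overlaps stayed above the value for independent lists, which does not allow for intensity. The Pearson r became 0.0466 with the 60th percentile floor; the cause was not tested. For embryonic cells 2 lists in place of 1 were higher with the 20th percentile floor, with only genes above the floor on both arrays, and without genes above 20000; for the array labelled Notch1 2 lists in place of 1 were lower without genes above 20000; the cause was not tested. Without genes above 20000 the ribosomal protein median of the array labelled Notch1 was -0.21 in place of 0.99. Most members were left out there, so the sign change compares different genes. Of 248 named gene results, 0 reversed and 62 dropped below 2-fold under some alternative. Of those with a fold or direction in the text, these dropped with the 60th percentile floor: Aloxe3, Col6a2, Crnkl1, Foxo4, H2-T18, Irf9, Itln1, Kifc1, Krt15, Krt77, Racgap1, Tcf7l2, Thbd and Vegfd for embryonic cells, and Alox12b, Aurkb, Cdkn2d, Irf1, Irf9, Isg15, Msx1, Plau, Rpl22, Scel, Tcf7l1, Tgfbi, Ube2c and Wnt3a for the array labelled Notch1. With the offset Aloxe3, Elovl6, Mx2, Tyrp1 and Wnt3a dropped for embryonic cells and Ivl for the array labelled Notch1, with the median over all probe sets Tyrp1 and Mki67 respectively, and with scaling to a common median Aloxe3 for embryonic cells and Hey1 for the array labelled Notch1, the latter also with quantile normalization and intensity-dependent centring. The other 104 alternative values of the counts, overlaps and list numbers stayed within 1.5 times of the reported value or, for the Pearson r, within its sampling interval. Among dim genes, between mean intensities of 568 and 1000, 28.6% and 39.0% were beyond 2-fold.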

Other observations

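All tests in this part were chosen after the data were seen. Fresh newborn cells and the GFP control culture differ in isolation, culture and infection at once, so their difference is given as values for 1 pair of arrays. Of 6057 genes measured on this pair, 643 were at least 2-fold higher in fresh newborn cells and 1025 at least 2-fold higher in the GFP culture. Proliferation genes stood higher in the GFP culture, 15 of 43 by at least 2-fold and 0 the other way, with a median log2 ratio of 0.44 over fresh cells: Mki67 was at least 11.6-fold, Hmgb2 7.96-fold and Top2a at least 6.94-fold higher. Involucrin (Ivl) was 9.99-fold higher in the GFP culture. Its newborn intensity of 323.4 lay just above the floor, so this fold is uncertain.

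Higher in fresh newborn cells were fibroblast markers, with a median of 1.04 and 10 of 19 at least 2-fold higher, cholesterol synthesis genes, with a median of 1.13 and 9 of 16, and immediate early and stress genes, with a median of 0.98 and 16 of 32. Lipid barrier genes had a median of 0.73, epidermal differentiation genes one of 0.67 and Wnt, hedgehog and hair follicle genes one of 0.56, all toward fresh cells. Notch3 was higher in fresh newborn cells too, by 3.23 on the log2 scale, so that the GFP array held the lowest Notch3 intensity of the 4 arrays, 298.6. Basal layer genes had a median of -0.11, inside the central 95% of random lists.

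A hypothesis that G2/M genes were lower and G1/S genes higher on the array labelled Notch1 was not decided. The G2/M list had 0 of 33 members at least 2-fold higher and 13 lower, with a median of -0.80 at percentile 0. The G1/S list had 8 of 29 higher and 0 lower, with a median of 0.30 at percentile 95.4, inside the central 95%. Some members had been seen before the lists were drawn up; without members described elsewhere, the 8 G2/M genes left lay at percentile 10.01 and the G1/S genes at 59.1, both inside the central 95%; this reduction was made after the full lists were tested and takes out genes with large differences. On the embryonic array 15 of 33 G2/M genes were at least 2-fold higher than on the newborn array, with a median of 0.90, and 2 of 29 G1/S genes, with a median of 0.13. Without members described elsewhere, all 8 G2/M genes left were above 0 there, with a median of 0.73 at percentile 99.1, and G1/S genes lay at percentile 47.4.

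A hypothesis that NF-kB targets stood higher on the array labelled Notch1 along with interferon genes was not borne out and stays undecided, since members went both ways. Of 17 measured NF-kB targets 4 were at least 2-fold higher and 6 lower, with a median of 0.15 at percentile 57.7. For embryonic against newborn cells 2 of 17 were higher and 3 lower, with a median of -0.16.

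Simple epithelium genes may be higher in both comparisons as a group, a hypothesis that came from Krt8 and Krt18. With all members the list median lay at percentile 100 in both: 12 of 23 were at least 2-fold higher on the embryonic array, with a median of 1.12, and 10 of 22 on the array labelled Notch1, with 2 lower and a median of 0.86. The list was drawn up after several members had been seen, so this test was bound to favour it. Without members described elsewhere, 10 genes were left in each comparison and lay at percentiles 68.7 and 94.3, inside the central 95%. This reduction was made after the full list was tested and takes out genes with large differences, so the hypothesis stays undecided.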
